A study of Mus musculus with 16 samples.

How the data were processed

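Per the labels, adipose progenitors came from the subcutaneous (SAT) and visceral (VAT) fat of mice 4 weeks old, either C57BL/6J wild type (WT) or carrying the Nr4a1tm1Jmi allele on a B6;129S2 background (KO). Each of the 4 groups held 4 libraries that the labels call biological replicates. Nothing in the labels says that the replicates are separate animals, so p-values measure only the spread between these samples. Sex, litter and preparation day are not given in the sources used here. The column names carry the word MACS, and the markers used for the sort are not given in the sources used here. Per the labels, RNA was purified with the RNeasy Micro kit, DNA was removed, libraries were made with the NEBNext Ultra RNA kit, and single reads were collected on an Illumina NextSeq instrument. That kit does not mark the strand of the RNA, so reads of genes that overlap on opposite strands cannot be told apart.

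The authors deposited a table of whole numbers per gene symbol and library, read here as counts of reads per gene, and all tests started from these counts. The authors also deposited a table of non-integer values of the unit signal. Where read above 50 counts, each of its values equalled the count divided by 1 factor per library, to within a relative deviation of 4.94e-10, and it was used only to recover those factors. Per the submitters' processing notes, STAR, FastQC, featureCounts and DESeq were used with genome build mm10. Program versions, the part DESeq played, the gene annotation, the strand setting and the handling of reads that map to several places are not given in the sources used here.

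The count table held 38720 lines, of which 27 carried names shaped like calendar dates, a trace of spreadsheet conversion, and 4 of these shared their names. These lines were kept in library totals and were never named. Gene positions and types came from GENCODE vM21 (GRCm38, the same assembly as mm10). A GENCODE symbol matched 35555 lines, a RefSeq synonym matched 1758, and 1407 had no match. Among tested genes 98.6% were matched.

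Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr, which left 16842, and libraries were scaled by TMM. A quasi-likelihood negative binomial model with 1 coefficient per group was fitted to all 16 libraries, with 12 residual degrees of freedom. Contrasts tested KO against WT in each depot, VAT against SAT in each genotype, and the difference between the KO effects of the depots (the interaction, VAT minus SAT). Adjusted p is the Benjamini-Hochberg adjusted p-value of that edgeR test over all tested genes, and genes were called at adjusted p under 0.05. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.156. CPM are counts scaled to a common library total after TMM scaling.

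Gene lists were written from general knowledge before the data were examined. They are: S phase and DNA replication, G2/M and mitosis, CDK inhibitors and quiescence-linked genes, immediate early genes, heat shock and dissociation stress, adipogenic transcription regulators, adipocyte lipid genes, thermogenic and beige markers, progenitor surface and identity markers, Dpp4-type interstitial progenitor genes, Icam1-type committed preadipocyte genes, F3-type regulator genes, extracellular matrix, cytokines with chemokines and NF-kB targets, type I interferon response, subcutaneous depot patterning, visceral depot patterning, nuclear oxidative phosphorylation, glycolysis and hypoxia targets, cholesterol synthesis, Wnt and TGF-beta/BMP signalling, sex-linked genes, mitochondrially encoded genes, and markers of macrophages and myeloid cells, lymphocytes, endothelium, mesothelium, pericytes and smooth muscle, Schwann and neural cells, epithelium and mammary gland, skeletal muscle, and erythroid cells. Each list was tested against all other genes with limma's camera on log2 CPM, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The same test was repeated with the correlation estimated from the residuals. Limma's fry tested whether the genes of a list shift together in the same direction, without comparison to other genes. Its separate mixed test asked whether they change in either direction. Calls of members were also adjusted over the list alone.

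Named genes followed a rule set before the data were examined. It took Nr4a1, Nr4a2 and Nr4a3. For each comparison it took the 8 largest increases and the 8 largest decreases among called protein-coding genes with a mean of at least 5 CPM over all libraries, no overlap in CPM between the groups, and no provisional name. It took up to 4 tested members with the smallest p-value of each described list, and for the interaction the 8 genes with the smallest p-value. Not all genes taken by this rule are reported here. The lists described for each comparison were chosen after the list tests were seen. Where a group summed to 0 counts over its libraries, the fold was given as a floor, taking 3 counts as the most that would give none. With 1 to 3 counts, the fold was given as a ratio with its 95% counting interval. Both cover counting error only.

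The procedure was tested on simulated data made from the fitted means and dispersions, with 200 genes changed. At changes of 1.5-fold, 2-fold and 4-fold it recovered 52.2%, 68.7% and 83.3% for KO against WT in SAT, 50.75%, 64.2% and 80.3% in VAT, 56.7%, 67.2% and 89.4% for VAT against SAT in WT, 50.75%, 68.7% and 80.3% in KO, and 26.9%, 67.2% and 77.3% for the interaction. False calls numbered 6 of 142, 5 of 135, 8 of 150, 10 of 143 and 4 of 118. A simulated list of 24 members raised by 0.5 on the log2 scale was found in each of 4 comparisons and no other list was called. Simulated genes were drawn independently of each other, so this could not show false list calls that arise from correlated genes.

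Alternatives tried were median-of-ratios and deposited size factors, DESeq2's Wald test, limma-voom, robust quasi-likelihood fitting, no low-count filter, a filter of 1 CPM in 4 libraries, fits to only the 8 libraries compared, a block for the replicate number, that block nested in genotype, each library left out in turn, a minimum change of 2-fold, and adjusted p under 0.01. Regrouping tests refitted every other split of the 8 libraries into groups of 4 for each comparison between groups. For the interaction, genotype was reassigned at random within each depot, giving 100 splits with the real one included. Enrichment of called genes near Nr4a1 was tested by Fisher's exact test in a window of 10 Mb on either side, with 5 and 20 Mb and DESeq2 calls as alternatives. A fit without WT SAT replicate 3 and KO VAT replicate 4 together was added after the data were seen.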

Results

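RNA sequencing libraries were collected from adipose progenitors, the fat-resident precursor cells that can become adipocytes, of mice 4 weeks old. The 4 groups crossed genotype, wild type (WT) or Nr4a1 knockout (KO), with depot, subcutaneous (SAT) or visceral (VAT) fat, and each held n = 4 libraries. Nr4a1 encodes an orphan nuclear receptor that many cells switch on as an immediate early gene. Total counts per library ranged from 34655519 to 49437944 in WT SAT, 44181663 to 55551845 in KO SAT, 42383156 to 46293781 in WT VAT and 35761196 to 43984232 in KO VAT. Of 38720 gene entries, 16842 passed the filter for low counts. Levels are given as mean CPM (counts scaled to a common library total) ± SD with n = 4, changes as log2 fold change ± SE, and adjusted p as the Benjamini-Hochberg adjusted value of the edgeR quasi-likelihood test.

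Nr4a1 (chromosome 15, 101254269 to 101274795, build mm10) stood at 1212, 1121, 1018 and 997 CPM in the WT SAT libraries and at 202, 209, 195 and 199 CPM in the KO SAT libraries. In VAT it stood at 1649, 1432, 1481 and 1581 CPM in WT and at 297, 327, 304 and 307 CPM in KO. The gene fell by 2.43 ± 0.08 on the log2 scale in KO SAT (adjusted p = 5.34e-12) and by 2.31 ± 0.08 in KO VAT (adjusted p = 5.53e-12). Counts are given per gene, so the part of Nr4a1 covered by the reads left in KO was not examined. Its relatives Nr4a2 and Nr4a3 were not called in SAT, at -0.13 ± 0.12 (adjusted p = 0.56) and -0.12 ± 0.18 (adjusted p = 0.729). In VAT, Nr4a2 (chromosome 2, 57106830 to 57124003) rose by 0.47 ± 0.12, from 141 ± 12.8 to 195 ± 19.4 CPM (adjusted p = 0.035), and Nr4a3 changed by 0.25 ± 0.18 without being called (adjusted p = 0.503). The Nr4a2 call was lost without WT VAT replicate 2, 3 or 4 or KO VAT replicate 1 or 2 (adjusted p from 0.0776 to 0.111), and its KO effects in the depots were not shown to differ (interaction 0.59 ± 0.17, adjusted p = 0.119).

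**Figure D1:**
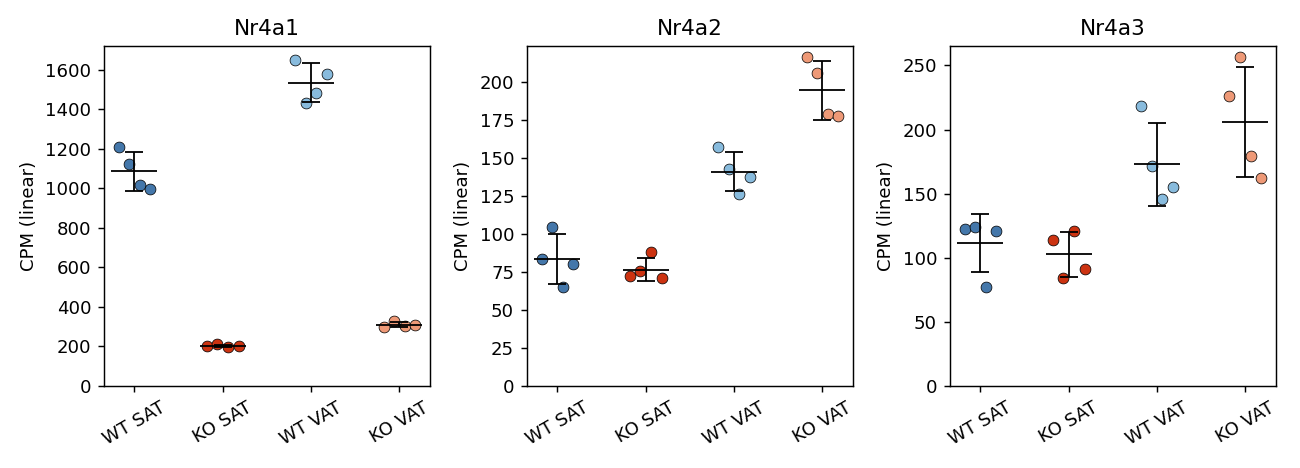
CPM of Nr4a1, Nr4a2 and Nr4a3 in each of the 16 libraries, by genotype and depot, with group mean ± SD. Nr4a1 was lower in every KO library than in any WT library, while levels of both relatives overlapped between genotypes in SAT.

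Depot separated the libraries more strongly than genotype. The first principal component of log2 CPM held 66.0% of the variance and placed all SAT libraries from -70.6 to -59.5 and all VAT libraries from 55.6 to 76.5. The second held 7.02%, on which every WT library was positive and every KO library negative. Across genes, which are not independent replicates, the median correlation of log2 CPM was 0.988 within groups, 0.984 between genotypes and 0.936 between depots. WT SAT replicate 3 and KO VAT replicate 4 lay farthest from their own groups, with mean correlations of 0.978 and 0.983. The collagen gene Col3a1 took 6.77 ± 0.786% of all counts in WT SAT, 8.59 ± 0.468% in KO SAT, 2.72 ± 0.193% in WT VAT and 3.54 ± 0.318% in KO VAT. Mitochondrial genes took 0.866 ± 0.192% and 0.935 ± 0.0860% in WT and KO SAT, and 1.14 ± 0.0917% and 1.32 ± 0.146% in WT and KO VAT. Xist, transcribed from an inactive X chromosome, had at most 17 counts in any library, and the Y-linked gene Ddx3y had at least 4754 in each. These counts are those of male tissue in every library, although the labels do not give sex, and they argue against a difference in sex between the groups.

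**Figure D2:**
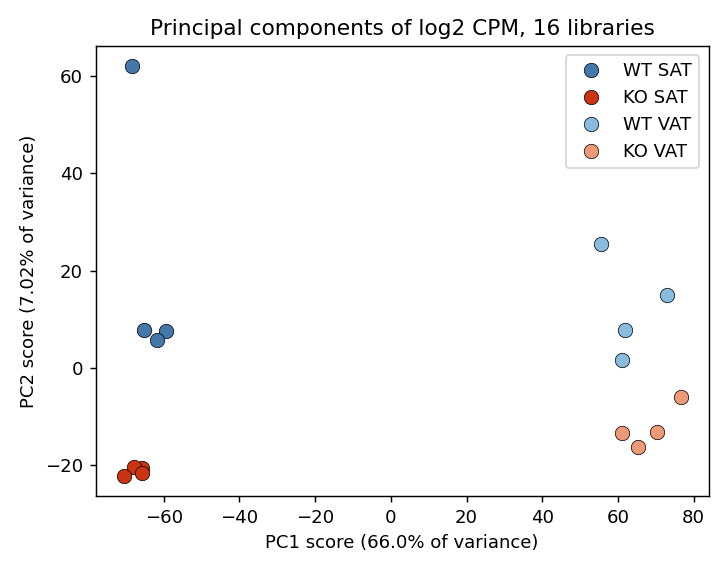
The 16 libraries on the first 2 principal components of log2 CPM, 1 point per library, marked by genotype and depot. Depots lay apart on the first axis and genotypes on the second, with WT SAT replicate 3 far from the other libraries.

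The first comparison asked which transcripts differed between KO and WT progenitors of subcutaneous fat. Genes of cell division were the most widely raised group in KO SAT. Of 36 tested genes of G2/M and mitosis, 35 rose (35 adjusted over the list alone), with a median of 1.48 on the log2 scale. Among them were the proliferation marker Mki67 (1.78 ± 0.16, adjusted p = 5.96e-06, from 7.24 ± 1.38 to 24.8 ± 4.06 CPM), the spindle gene Hmmr (1.80 ± 0.15, adjusted p = 3.18e-06) and cyclin A2, Ccna2 (1.57 ± 0.14, adjusted p = 5.96e-06). Cenpf, needed at kinetochores, rose by 1.77 ± 0.21 (adjusted p = 0.000119). Of 34 genes of S phase and DNA replication, 12 rose (18 adjusted over the list alone). These included Uhrf1, which maintains DNA methylation at replication (1.16 ± 0.14, adjusted p = 0.00013), the ribonucleotide reductase genes Rrm2 (1.01 ± 0.15, adjusted p = 0.000679) and Rrm1 (0.44 ± 0.06, adjusted p = 0.000163), and Tk1 (0.61 ± 0.10, adjusted p = 0.002). Cdkn2c, which encodes a CDK inhibitor, also rose (0.66 ± 0.08, adjusted p = 0.000163), as did Sesn3 (0.67 ± 0.16, adjusted p = 0.0216), whose call was lost without KO SAT replicate 2, 3 or 4 (adjusted p from 0.0575 to 0.0694). In the list test the G2/M genes were raised beyond other genes (adjusted p = 2.20e-54, and 0.0282 with an estimated correlation). S phase genes were raised with the preset correlation only (adjusted p = 1.07e-11, and 0.0957 with an estimated correlation).

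Interferon-response genes were also higher in KO SAT. Of 28 tested, 16 rose (24 adjusted over the list alone), with a median of 0.58 (adjusted p = 4.69e-18, and 0.117 with an estimated correlation). Stat2, which carries the type I interferon signal to the nucleus, went from 77.8 ± 8.93 to 116 ± 2.44 CPM (0.58 ± 0.08, adjusted p = 0.000205). The RNA sensor gene Ifih1 rose by 0.62 ± 0.09 (adjusted p = 0.000681), Gbp3 by 0.83 ± 0.12 (adjusted p = 0.000537) and Ifit2 by 0.59 ± 0.09 (adjusted p = 0.000712). Reads of the Ifit and Gbp families are shared among similar copies, which leaves the values of single members uncertain.

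Stress and adipogenic regulators moved the other way in KO SAT. Of 16 genes of heat shock and dissociation stress, 6 fell (10 lower and 1 higher adjusted over the list alone; adjusted p = 1.66e-06, and 0.117 with an estimated correlation). They included the small heat shock protein gene Hspb1 (-0.93 ± 0.13, adjusted p = 0.000449, from 90.3 ± 18.4 to 47.2 ± 6.76 CPM), Hsph1 (-0.48 ± 0.07, adjusted p = 0.000472), and the near-identical Hspa1a (-0.74 ± 0.09, adjusted p = 0.00013) and Hspa1b (-0.70 ± 0.09, adjusted p = 0.000119), whose reads cannot be assigned with certainty. Of 25 adipogenic transcription regulators 5 fell, and 2 without KO SAT replicate 3 or 4 (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00757, and 0.117 with an estimated correlation). Klf15, a regulator of lipid and amino acid use, went from 32.1 ± 2.54 to 17.9 ± 2.09 CPM (-0.84 ± 0.09, adjusted p = 7e-05). Cebpd, which acts early in adipogenesis, fell by 0.75 ± 0.13 (adjusted p = 0.00302). Immediate early genes were lower as a list (adjusted p = 0.00332, and 0.441 with an estimated correlation), with Junb (-0.37 ± 0.07, adjusted p = 0.00541) and Maff (-0.49 ± 0.10, adjusted p = 0.00963) down and Egr2 up (0.64 ± 0.12, adjusted p = 0.00414). Glycolysis and hypoxia targets were lower (adjusted p = 0.00137, and 0.0957 with an estimated correlation), among them the aldolase gene Aldoa (-0.36 ± 0.07, adjusted p = 0.0072) and the mitophagy gene Bnip3 (-0.48 ± 0.10, adjusted p = 0.0101).

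Progenitor subtype and matrix genes split in KO SAT. Within the Dpp4-type interstitial progenitor list, the alarmin gene Il33 went from 54.8 ± 7.88 to 101 ± 7.26 CPM (0.88 ± 0.10, adjusted p = 7.73e-05) and Sema3c rose by 0.65 ± 0.12 (adjusted p = 0.00404). That list was raised (adjusted p = 0.00381, and 0.617 with an estimated correlation), a call lost without WT SAT replicate 4 (adjusted p = 0.0663). Of its 20 tested genes 4 rose and 1 fell, and 2 to 3 rose in fits that left out a library. The Icam1-type committed preadipocyte list was lower (adjusted p = 0.00777, and 0.356 with an estimated correlation; 0.063 without KO SAT replicate 2), with falls in Hsd11b1, which regenerates active glucocorticoid (-0.91 ± 0.17, adjusted p = 0.00377), and angiotensinogen, Agt (-0.83 ± 0.16, adjusted p = 0.00452). Among the 20 tested Icam1-type genes 3 fell and 1 rose, and 2 to 4 fell in fits that left out a library. Of the 14 F3-type regulator genes 3 fell, and 5 without KO SAT replicate 2 (7 adjusted over the list alone; adjusted p = 0.000562, and 0.117 with an estimated correlation), including Cygb (-0.47 ± 0.07, adjusted p = 0.000716) and Fmo2 (-0.89 ± 0.17, adjusted p = 0.00474). The matrix genes Fbn2 (1.45 ± 0.22, adjusted p = 0.000659), Postn (0.75 ± 0.12, adjusted p = 0.00102) and Eln (0.73 ± 0.16, adjusted p = 0.0101) rose, and Fbln1 fell (-0.38 ± 0.09, adjusted p = 0.0132; 0.0589 without KO SAT replicate 4). Of 38 tested matrix genes 4 rose and 3 fell (6 and 4 adjusted over the list alone), and the count that fell was 1 without KO SAT replicate 1 or 2 and 0 without KO SAT replicate 4. The extracellular matrix list was not called (adjusted p = 0.0643), but it was without WT SAT replicate 1 or 4 or KO SAT replicate 1 or 4 (adjusted p from 0.0287 to 0.0431). The secreted ligand genes Wnt4 (-2.09 ± 0.32, adjusted p = 0.000797) and Inhbb (-0.82 ± 0.17, adjusted p = 0.0101) fell, while the Wnt and TGF-beta/BMP list did not shift (adjusted p = 0.312). Gelsolin, Gsn, a broad fibroblast gene, went from 44609 ± 7990 to 26691 ± 2301 CPM (-0.74 ± 0.11, adjusted p = 0.00071).

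Among called protein-coding genes with a mean of at least 5 CPM over all libraries, an established name and no overlap between the groups, the immunoglobulin J chain gene Igj rose most in KO SAT (3.98 ± 1.02, adjusted p = 0.029). That call was lost without any of the WT SAT libraries or without KO SAT replicate 2 or 4 (adjusted p from 0.0576 to 0.0895). Next came the protease gene Adamts19 (2.02 ± 0.18, adjusted p = 6.13e-06, from 0.912 ± 0.203 to 3.73 ± 0.485 CPM) and the homeobox gene Alx4 (1.99 ± 0.25, adjusted p = 0.00013). Under the same limits and apart from Nr4a1, the largest decreases with calls kept in every fit were the bicarbonate transporter gene Slc4a8 (-1.49 ± 0.16, adjusted p = 4.29e-05), Tsc22d3, a glucocorticoid-induced gene (-1.40 ± 0.19, adjusted p = 0.000264, from 375 ± 119 to 142 ± 28.6 CPM), Nmb (-1.31 ± 0.24, adjusted p = 0.00338), Igfbp3 (-1.27 ± 0.28, adjusted p = 0.0113) and Map7d2 (-1.24 ± 0.18, adjusted p = 0.000496). Slc4a8 lies within 10 Mb of Nr4a1, where a gene-targeted strain can carry flanking DNA of another background. Cxcl13 and Trem2 fell by 1.30 ± 0.34 (adjusted p = 0.0323) and 1.26 ± 0.33 (adjusted p = 0.0318). The Cxcl13 call was lost without WT SAT replicate 3 or 4 or any KO SAT library (adjusted p from 0.0562 to 0.0914), and the Trem2 call without WT SAT replicate 2 or 3 or any KO SAT library (adjusted p from 0.0572 to 0.0949).

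Markers of some other cell types were also lower in KO SAT. The pericyte and smooth muscle list was lower (median -0.44, 3 of 15 called lower and 8 adjusted over the list alone, adjusted p = 9.81e-05, and 0.305 with an estimated correlation). Its count of 3 was 1 without WT SAT replicate 1 or 2 or KO SAT replicate 3, 0 without WT SAT replicate 3 or KO SAT replicate 2 or 4, and 6 without WT SAT replicate 4. The Schwann and neural list was lower (median -0.32, adjusted p = 0.0451, and 0.617 with an estimated correlation), which was lost without WT SAT replicate 2, 3 or 4 or KO SAT replicate 2 or 3 (adjusted p up to 0.293). Lists of macrophages and myeloid cells (adjusted p = 0.162), lymphocytes (0.487), endothelium (0.835), mesothelium (0.453), epithelium and mammary gland (median -0.49; 0.57), skeletal muscle (0.993) and erythroid cells (0.682) were not called, although the macrophage list was without WT SAT replicate 2 (adjusted p = 0.0121). The sex-linked list was higher (median 0.33, adjusted p = 0.0339, and 0.198 with an estimated correlation) and was lost without WT SAT replicate 1 or KO SAT replicate 3 (adjusted p up to 0.0782). Nuclear oxidative phosphorylation was lower as a list (median -0.21, adjusted p = 1.33e-05, and 0.617 with an estimated correlation), with 0 of 33 genes called by edgeR (12 at unadjusted p under 0.05; 1 called by DESeq2 and 0 by limma-voom). Lists of CDK inhibitors (adjusted p = 0.0643), adipocyte lipid genes (0.107), thermogenic markers (0.312), progenitor identity markers (0.993), cytokines (0.99), subcutaneous (0.424) and visceral (0.856) patterning, cholesterol synthesis (0.682) and mitochondrially encoded genes (0.121) were not called. Some of these calls appeared when a library was left out: CDK inhibitors without WT SAT replicate 3 or KO SAT replicate 1 or 4 (adjusted p from 0.0374 to 0.0476), lipid genes without KO SAT replicate 4 (0.0248), and mitochondrial genes without WT SAT replicate 2 or KO SAT replicate 2 (0.0101 and 0.0496). The median and the test differed in sign for the cytokine and skeletal muscle lists (medians -0.01 and -0.25, tests upward).

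In total, edgeR called 992 genes in SAT, 582 higher and 410 lower in KO, and 208 of the higher and 43 of the lower genes changed at least 2-fold. Leaving out KO SAT replicate 2, 3 or 4 reduced the total to 579, 661 and 469, a fit to only the SAT libraries gave 509, and DESeq2 gave 1665. Genotype was not separable from strain background, litter or day of preparation, so each difference belongs to the groups as collected.

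**Figure D3:**
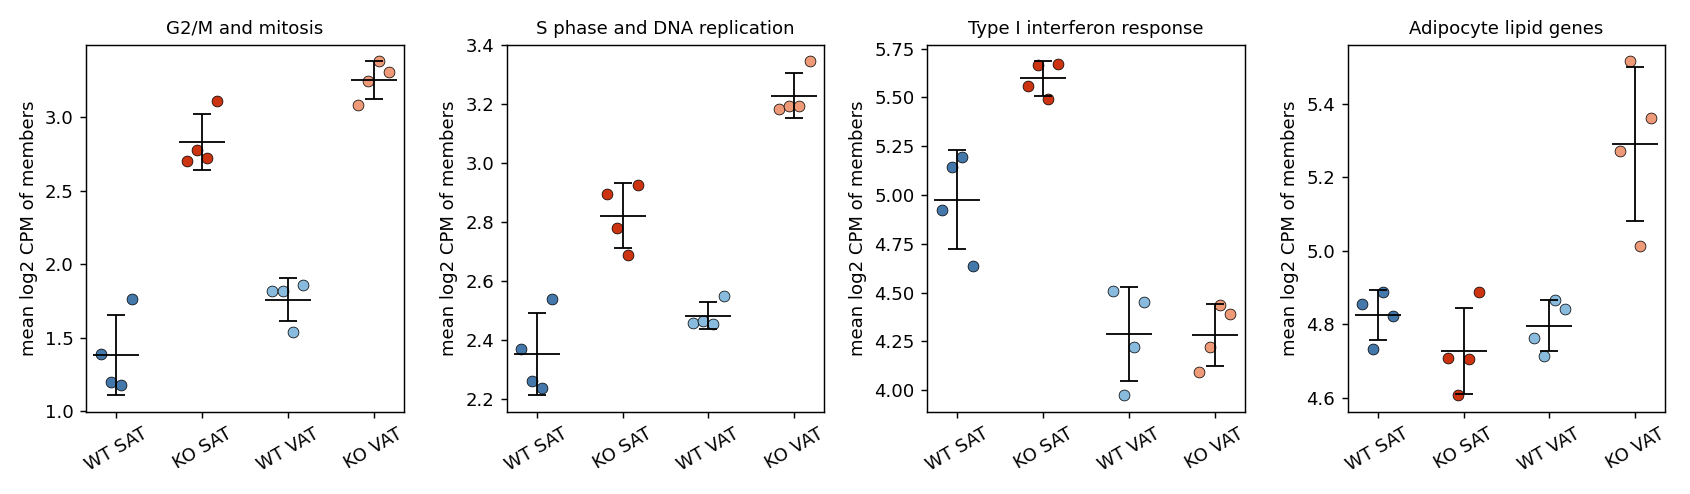
Mean log2 CPM of the members of 4 gene lists in each library, by genotype and depot. Mitotic genes lay higher in KO in both depots, while the higher levels of interferon genes in KO SAT and lipid genes in KO VAT were list calls lost with an estimated correlation.

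The same question was asked of visceral progenitors. Cell division genes rose there too. All 36 G2/M and mitosis genes were called higher (36 adjusted over the list alone), with a median of 1.60 (adjusted p = 3.94e-68, and 0.00565 with an estimated correlation). Mki67 went from 9.49 ± 1.42 to 33.4 ± 5.08 CPM (1.82 ± 0.15, adjusted p = 3.71e-06), Top2a, which untangles chromosomes, rose by 1.78 ± 0.17 (adjusted p = 1.38e-05), and Cdk1 rose by 1.63 ± 0.14 (adjusted p = 3.71e-06). The mitotic motor gene Cenpe rose by 1.88 ± 0.21 (adjusted p = 3.99e-05). Of 34 S phase genes 24 rose, and 16 to 22 in fits that left out a library (30 adjusted over the list alone; adjusted p = 2.19e-31, and 0.00565 with an estimated correlation). Examples were Tk1 (1.15 ± 0.10, adjusted p = 4.54e-06), Uhrf1 (1.38 ± 0.14, adjusted p = 1.63e-05), Rrm2 (1.25 ± 0.15, adjusted p = 8.01e-05) and Dtl (1.58 ± 0.19, adjusted p = 8.83e-05). Cdkn2c again rose (0.93 ± 0.08, adjusted p = 5.59e-06), and the list of CDK inhibitors was lower (adjusted p = 0.0283, and 0.192 with an estimated correlation), a call lost without WT VAT replicate 4 or KO VAT replicate 4 (adjusted p up to 0.0544).

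Genes of adipocyte lipid storage were higher in KO VAT. Of 30 tested, 11 rose and none fell (14 adjusted over the list alone), with a median of 0.33 (adjusted p = 2.58e-09, and 0.175 with an estimated correlation). The lipid droplet coat gene Plin1 went from 35.9 ± 3.72 to 93.7 ± 20.6 CPM (1.38 ± 0.17, adjusted p = 9.52e-05) and the adipokine gene Adipoq from 18.9 ± 2.77 to 53.5 ± 13.6 CPM (adjusted p = 0.00124). Car3 rose by 1.39 ± 0.18 (adjusted p = 0.000174), and Gpd1, which lies within 10 Mb of Nr4a1, rose by 1.56 ± 0.25 (adjusted p = 0.00123). Lgals12, a galectin gene of lipid droplets, rose by 1.75 ± 0.18 (adjusted p = 2.86e-05). Among thermogenic and beige markers Slc36a2 (1.53 ± 0.13, adjusted p = 4.18e-06) and Dio2 (1.40 ± 0.26, adjusted p = 0.00403) rose. That list was raised (adjusted p = 0.0143, and 0.286 with an estimated correlation), a call lost without WT VAT replicate 4 or KO VAT replicate 2 (adjusted p up to 0.0547). Cholesterol synthesis genes were raised as a list (median 0.37, adjusted p = 1.26e-07, and 0.232 with an estimated correlation), with 2 of 24 called, 0 to 4 in fits that left out a library, and 13 adjusted over the list alone.

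Several regulators fell in KO VAT. Klf15 fell by 0.61 ± 0.09 (adjusted p = 0.000699), while Cebpa, a driver of adipocyte identity, rose by 0.58 ± 0.13 (adjusted p = 0.0152; 0.0525 to 0.0594 without WT VAT replicate 1 or 3 or KO VAT replicate 2 or 4), and adipogenic regulators did not shift as a list (adjusted p = 0.777; median 0.05, test downward). Heat shock genes were lower as a list (adjusted p = 0.00669, and 0.446 with an estimated correlation; 0.0669 without KO VAT replicate 3), with Hspa1b (-0.49 ± 0.09, adjusted p = 0.00237) and Hspa1a (-0.42 ± 0.09, adjusted p = 0.0128) down. Immediate early genes were lower as a list (adjusted p = 0.0159, and 0.563 with an estimated correlation). Inhbb, which encodes an activin subunit, fell by 0.94 ± 0.13 (adjusted p = 0.00034), the visceral patterning gene Osr1 by 0.57 ± 0.10 (adjusted p = 0.00333) and the vasoactive peptide gene Adm by 0.56 ± 0.11 (adjusted p = 0.00556). Dpp4-type genes were lower (adjusted p = 0.00669, and 0.622 with an estimated correlation; 0.142 without KO VAT replicate 4). F3-type genes were lower (adjusted p = 0.0283, and 0.437 with an estimated correlation), which was lost without WT VAT replicate 1 or KO VAT replicate 2 (adjusted p up to 0.0962). Large decreases besides Nr4a1 were Gpr165 (-2.09 ± 0.31, adjusted p = 0.000558), H2-M9 (-1.33 ± 0.22, adjusted p = 0.00181), Vat1l (-1.23 ± 0.26, adjusted p = 0.0101), Rasl10b (-1.13 ± 0.14, adjusted p = 0.000104), Galnt15 (-1.08 ± 0.13, adjusted p = 7.97e-05) and the lubricin gene Prg4 (-1.08 ± 0.16, adjusted p = 0.000558).

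Interferon-response genes showed no call in KO VAT: edgeR called 0 of 28 (3 at unadjusted p under 0.05; DESeq2 and limma-voom called 1 each), and the list test gave adjusted p = 0.841 (0.953 with an estimated correlation and 0.94 by fry), with Stat2 at 0.19 ± 0.08 (adjusted p = 0.189). Lymphocyte markers were higher as a list (adjusted p = 0.0143, and 0.437 with an estimated correlation), with the immunoglobulin gene Ighm up by 1.68 ± 0.38 (adjusted p = 0.0165; 0.063 without WT VAT replicate 4). Mitochondrially encoded genes were higher (adjusted p = 0.0223, and 0.561 with an estimated correlation), which was lost without WT VAT replicate 1 or KO VAT replicate 3 (adjusted p up to 0.136). No call was made for progenitor identity (adjusted p = 0.129), Icam1-type genes (0.643), extracellular matrix (0.643), cytokines (0.643), subcutaneous (0.643) and visceral (0.453) patterning, nuclear oxidative phosphorylation (0.0749), glycolysis (0.643), Wnt and TGF-beta/BMP signalling (0.0557) and sex-linked genes (0.706). Nor was one made for markers of macrophages (0.777), endothelium (0.643), mesothelium (0.0691), pericytes (0.668), Schwann cells (0.238), epithelium (0.493), skeletal muscle (0.646) and erythroid cells (0.129). Leaving out a library gave calls for matrix genes without KO VAT replicate 4 (adjusted p = 0.0258), for oxidative phosphorylation without WT VAT replicate 3 or 4 or KO VAT replicate 3 (0.0195, 0.0179 and 0.0199), and for Wnt and TGF-beta/BMP genes without WT VAT replicate 3 or KO VAT replicate 3 or 4 (0.0181, 0.0361 and 0.0263). It also gave calls for mesothelial markers without WT VAT replicate 2 or KO VAT replicate 3 or 4 (0.0016, 0.00443 and 0.0263) and for erythroid markers without WT VAT replicate 2, 3 or 4 (0.0137, 0.0194 and 0.0179). The macrophage list had a median of -0.13 and an upward test.

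In VAT, edgeR called 690 genes, 478 higher and 212 lower in KO, of which 249 and 24 changed at least 2-fold. Leaving out WT VAT replicate 1 or 4 or KO VAT replicate 4 reduced the total to 426, 455 and 412, and DESeq2 gave 1206. The limits on what the genotype contrast separates are those given for SAT.

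The KO effects of the depots were then set side by side. Of the called genes, 199 were higher in KO in both depots against 16.5 expected by chance from the separate totals, 67 were lower in both against 5.12, and 3 went opposite ways against 18.9. The expected numbers treat the depots and the genes as independent. Strain background went with genotype in both depots, and SAT and VAT libraries may come from the same mice. The excess therefore does not separate a KO effect from these. Mki67, Pbk, Iqgap3 and Cenpf were among the 8 largest increases of both depots under the limits on level, name, coding type and overlap given for SAT. Across 16841 genes, which are not independent replicates, the effects correlated at 0.244 (Pearson) and 0.122 (Spearman). Near Nr4a1, where a gene-targeted strain can carry flanking DNA of another background, 15 of 168 genes within 10 Mb were called in SAT (8.93% against 5.89% elsewhere; odds ratio 1.57, 0.852 to 2.68, Fisher's exact p = 0.0997). In VAT 14 of 168 were called (8.33% against 4.04%; odds ratio 2.16, 1.15 to 3.76, Fisher's exact p = 0.00993), and the excess was not called at 20 Mb (1.631, exact p = 0.0647) or with DESeq2 calls (1.455, exact p = 0.135), but was at 5 Mb (2.466, exact p = 0.00512) and without WT SAT replicate 3 and KO VAT replicate 4 together (1.901, exact p = 0.0289), a fit added after the data were seen. Genes in such a window are not independent, so these p-values are approximate.

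**Figure D4:**
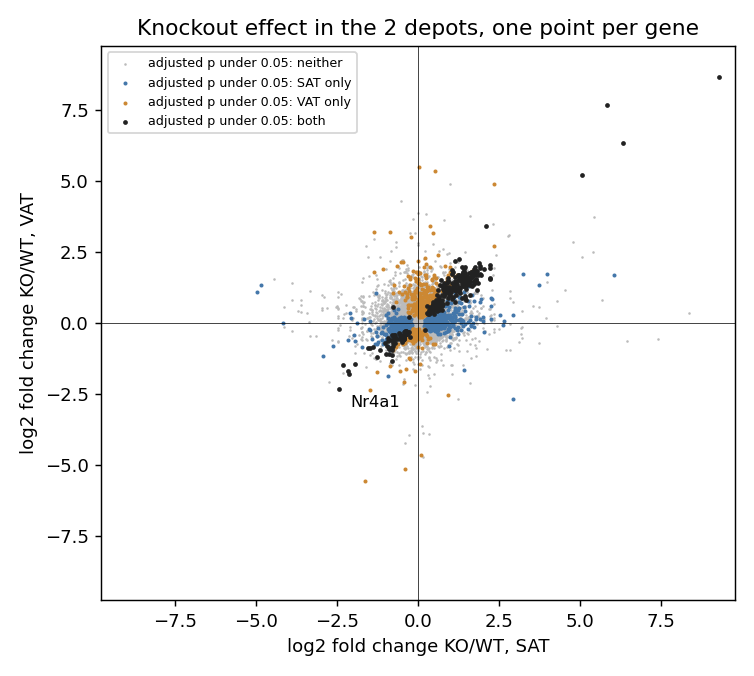
Log2 fold change of KO against WT in SAT and in VAT, 1 point per tested gene, coloured by where it was called. Nr4a1 was low in both, and points at the edges are genes near 0 counts in a group, whose fitted change depends on the prior count.

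Whether the KO effect differed between depots was tested directly by the interaction. By the list test with the preset correlation, lipid and interferon genes had the smallest p-values, and edgeR called 0 genes of the cell division lists. Unadjusted p was under 0.05 for 5 G2/M genes and 9 S phase genes, and DESeq2 called 0 and 2 and limma-voom 0 and 0. Adamts19 rose in SAT only (2.02 against 0.08 in VAT; interaction -1.94 ± 0.23, adjusted p = 0.00434). The interferon-induced gene Ifit2 differed by -0.91 ± 0.13 (adjusted p = 0.0135), as did Ifih1 (-0.82 ± 0.13, adjusted p = 0.0202) and Trim30a (-1.04 ± 0.17, adjusted p = 0.0202). The Ifih1 call was lost without WT SAT replicate 1 or KO SAT replicate 4 (adjusted p from 0.0506 to 0.0561), and the Trim30a call without those or KO VAT replicate 2 (adjusted p from 0.0518 to 0.0614). Both calls were also lost with a block for the replicate number. Lgals12 differed by 1.70 ± 0.26 (adjusted p = 0.0141), Stac2 by -1.48 ± 0.21 (adjusted p = 0.0135), the cell cycle regulator gene Rgcc by 1.33 ± 0.20 (adjusted p = 0.0141), and Ppp1r1a, within 10 Mb of Nr4a1, by 1.52 ± 0.24 (adjusted p = 0.02).

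As lists, adipocyte lipid genes had a higher KO effect in VAT (median 0.57, 3 of 30 called and 16 adjusted over the list alone, adjusted p = 5.94e-10, and 0.208 with an estimated correlation; 0.0144 by fry). The count of 3 was 0 without WT SAT replicate 1 or 4, WT VAT replicate 3, KO SAT replicate 1, 2 or 4, or KO VAT replicate 2 or 4, and 1 without WT VAT replicate 1 or 4 or KO SAT replicate 3. It was 6 without WT SAT replicate 2 and 11 without KO VAT replicate 3. Interferon genes had a lower KO effect in VAT (median -0.57, 3 of 28 called and 17 adjusted over the list alone, adjusted p = 9.29e-15, and 0.312 with an estimated correlation; 0.0404 by fry). Their count of 3 was 1 without WT SAT replicate 1 or KO SAT replicate 4, and 6 without WT VAT replicate 2 or KO VAT replicate 3. Lists of Dpp4-type genes (adjusted p = 5.88e-07 and 0.429), oxidative phosphorylation (5.88e-07 and 0.586), S phase (6.27e-05 and 0.429), pericytes (0.000375 and 0.464), cholesterol synthesis (0.00045 and 0.464) and glycolysis (0.00203 and 0.208) differed with the preset correlation and not with an estimated correlation. The G2/M list did not differ (median 0.07, adjusted p = 0.597, and 0.912 with an estimated correlation). The calls of the lists of Icam1-type (adjusted p = 0.00894, and 0.464 with an estimated correlation), heat shock (0.0174, and 0.575) and adipogenic genes (0.0369, and 0.428) were lost when a library was left out. These were KO VAT replicate 2 for Icam1-type (0.0563), WT VAT replicate 2, KO SAT replicate 3 or KO VAT replicate 1 for heat shock (up to 0.0826), and WT SAT replicate 4, WT VAT replicate 3 or 4, KO SAT replicate 1 or KO VAT replicate 2 for adipogenic genes (up to 0.14).

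In total edgeR called 45 genes for the interaction, 22 higher and 23 lower, and DESeq2 called 512. With a replicate block edgeR called 14, and 11 with the block nested in genotype. The total fell to 10, 12, 16, 14 and 21 without WT SAT replicates 1 and 4 and WT VAT replicates 1, 3 and 4, each left out alone. It fell to 23, 21, 17 and 7 without KO SAT replicates 1 to 4, to 24, 15 and 17 without KO VAT replicates 1, 2 and 4, and rose to 149 without KO VAT replicate 3. Small differences between depots were seldom within reach, as 26.9% of simulated 1.5-fold differences were recovered.

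The depots themselves were compared within each genotype, to ask which genes mark visceral against subcutaneous progenitors. Positional genes of the lists fixed beforehand differed widely. Of 22 visceral patterning genes 18 were higher in VAT in WT, and 18 in KO (18 adjusted over the list alone in each; medians 1.12 and 1.07; adjusted p = 5.66e-13 and 6.92e-11). The transcription factor gene Tcf21 differed by 8.06 ± 0.18 in WT (adjusted p = 6.48e-15, from 0.574 to 153 CPM) and by 8.39 ± 0.19 in KO, and Hoxa5 by 2.34 ± 0.11 in WT (adjusted p = 4.67e-11). Of 20 subcutaneous patterning genes 13 were lower and 4 higher in VAT in WT, and 14 lower and 5 higher in KO (the same adjusted over the list alone; adjusted p = 1.85e-06 and 5.47e-05). Tbx15 went from 130 to 0.266 CPM in WT (-8.92 ± 0.18, adjusted p = 1.62e-15), and Shox2 (-3.72 ± 0.11) and En1 (-5.23 ± 0.22) were lower too. With an estimated correlation visceral patterning (adjusted p = 0.000894 in WT and 0.00222 in KO) and subcutaneous patterning (0.0139 and 0.0421) kept their calls.

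Mesothelial markers formed the largest depot difference. All 16 were higher in VAT in both genotypes (16 adjusted over the list alone; medians 6.40 and 7.98; adjusted p = 9.42e-21 and 3.31e-18, and 0.0139 and 0.0333 with an estimated correlation). Such genes are expressed by the epithelium that covers visceral fat. The uroplakin gene Upk3b reached 495 CPM in WT VAT (11.87 ± 0.44 over WT SAT), and Slpi reached 290 CPM (11.33 ± 0.40). Bnc1 had 0 counts in WT SAT, which places it at least 1609-fold higher in WT VAT, and Muc16 was at least 1032-fold higher in WT and 584-fold in KO. Wt1, which marks mesothelium and visceral progenitors, had 1 count over the WT SAT libraries, a ratio of 15960 (2864 to 630300), and Upk1b likewise had a ratio of 18520 (3323 to 731400). These floors and intervals cover counting error only. The difference in mesothelial RNA between depots accompanies every other depot difference given here.

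Dpp4-type progenitor, matrix, interferon and Schwann genes were mostly lower in VAT. Of 20 Dpp4-type genes, 18 were lower in WT and 19 in KO (18 and 19, with 1 higher in each, adjusted over the list alone; adjusted p = 4.07e-13 and 7.78e-16, and 0.102 and 0.0922 with an estimated correlation), among them Pi16 (-2.41 ± 0.15 in WT, -2.72 ± 0.16 in KO) and Opcml (-2.57 ± 0.14 in WT). Of 28 interferon genes 18 were lower and 1 higher in WT, and 27 were lower in KO (19 lower and 1 higher, and 27 lower, adjusted over the list alone; adjusted p = 4.72e-07 and 2.23e-15, and 0.413 and 0.155 with an estimated correlation). Usp18, a brake on interferon signalling, differed by -2.63 ± 0.18 in WT and -2.91 ± 0.18 in KO. Of 38 matrix genes 22 were lower and 8 higher in WT, and 24 lower and 7 higher in KO (adjusted over the list alone 23 and 8, and 27 and 7; adjusted p = 0.0001 and 2.10e-05, and 0.413 and 0.333 with an estimated correlation), including Mmp2 (-1.82 ± 0.09 in WT) and Col1a1 (-2.03 ± 0.11 in WT). Schwann and neural markers were lower (adjusted p = 3.93e-08 and 1.21e-06, and 0.102 and 0.155 with an estimated correlation). Of 12 thermogenic markers 8 were lower in WT (adjusted p = 1.85e-05, and 0.0450 with an estimated correlation), including Tmem26 (-3.19 ± 0.15), and 6 were lower and 2 higher in KO (adjusted p = 0.00368, and 0.173 with an estimated correlation), with the same counts adjusted over the list alone.

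Further lists differed between depots less uniformly. Pericyte and smooth muscle markers were higher in VAT in WT and KO (adjusted p = 0.000156 and 2.87e-06, and 0.413 and 0.222 with an estimated correlation), with desmin, Des, up by 1.22 ± 0.15 in WT. G2/M genes were higher in VAT (adjusted p = 0.00496 and 0.0017, and 0.754 and 0.589 with an estimated correlation). In KO, S phase genes (20 higher and 1 lower of 34, adjusted p = 0.0012, and 0.369 with an estimated correlation), lipid genes (18 higher and 4 lower of 30, adjusted p = 0.00466, and 0.419 with an estimated correlation) and cholesterol synthesis (adjusted p = 0.0109, and 0.494 with an estimated correlation) were higher in VAT, with the same S phase and lipid counts adjusted over the list alone. The corresponding WT lists were not called (adjusted p = 0.321, 0.636 and 0.646). Lipase, Lipe, was higher by 1.12 ± 0.14 and Car3 by 1.44 ± 0.18 in KO VAT, whereas Plin4 was lower (-0.94 ± 0.12). Heat shock genes were lower in VAT in WT (adjusted p = 0.00335, and 0.413 with an estimated correlation), with Hsph1 at -0.92 ± 0.07, and the list was not called in KO (0.101). Epithelial markers were higher in WT (adjusted p = 0.0303, and 0.609 with an estimated correlation; up to 0.073 without WT SAT replicate 3 or WT VAT replicate 2) and KO (0.00368, and 0.369 with an estimated correlation). In the lists of Wnt and TGF-beta/BMP and F3-type genes, members went both ways, such as Inhbb (4.37 ± 0.16), Bmp7 (-2.26 ± 0.16), Rspo1 (4.15 ± 0.25) and Epha3 (-1.47 ± 0.16) in WT, and neither list was called (0.723 and 0.225 in WT, 0.979 and 0.102 in KO).

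In total edgeR called 6187 genes between depots in WT, 3217 higher and 2970 lower in VAT, and 7292 in KO, 3922 higher and 3370 lower. List calls that held with an estimated correlation were G2/M in SAT, G2/M and S phase in VAT, both patterning lists and mesothelial markers between depots in each genotype, and thermogenic markers between depots in WT. None held for the interaction, where the smallest adjusted p with an estimated correlation was 0.208. No list call other than these is shown to exceed what correlated genes could give. Limma's fry asked instead whether the genes of a list shift together in 1 direction. By fry 8 lists passed in SAT, 5 in VAT, 20 and 22 between depots in WT and KO, and 3 for the interaction. Its test of change in either direction passed 21 lists in SAT, 18 in VAT, 28 between depots in each genotype, and 15 for the interaction.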

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

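The rules for values set apart from their group were fixed before the values were seen, and no test of a cause was made for them. Groups of 4 libraries were examined for CPM of named genes, total counts, and shares of counts in Col3a1 and the most counted genes. By chance about 1 in 20 groups would hold a value set apart. Among these 490 groups, 32 values (6.53%) lay apart from the other libraries of their group, all of them CPM of named genes. In WT SAT these were, in CPM, Nr4a3 at 77.39 in replicate 3 (others 120.7 to 124.2), Klf9 at 640.5, Arl4a at 183.8, Psmb8 at 52.81 and Aldoa at 571 in replicate 3. The same held for Upk1b and Wt1 at 0.02553 each and Tcf21 at 0.97 in replicate 2, Gdf10 at 715.1 and Hoxc10 at 37.46 in replicate 1, and Usp18 at 25.45 in replicate 4. In KO SAT they were Ect2 at 6.292, Sesn3 at 10.13 and Gsn at 30110 in replicate 1, Upk1b at 0 and Agt at 66.81 in replicate 2, Cebpb at 136.7 in replicate 3 and Gdf10 at 351.2 in replicate 4. In WT VAT they were Hsph1 at 69.57 and Dcn at 9352 in replicate 1, Lhx8 at 0.02076, Wnt2b at 43.59 and Ncmap at 1.245 in replicate 2, and Tmem28 at 0.05939, Jun at 2983 and Hoxa5 at 52.91 in replicate 3. In KO VAT they were E2f1 at 12.89, Cdk1 at 11.02 and Usp18 at 5.277 in replicate 1, Gzma at 0.5058 in replicate 2, Gsn at 16660 in replicate 3 and Cited1 at 4.972 in replicate 4. The values of Upk1b, Wt1 and Lhx8 rest on single counts or none, so their distance from the group is within counting error. WT SAT replicate 3 held 5 of the 32 values and was also the library with the fewest counts.

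Named genes whose KO effect differed between the depots had these log2 differences, VAT minus SAT: Adamts19 -1.938, Ifit2 -0.9089, Stac2 -1.477, Rgcc 1.333, Lgals12 1.703, Ppp1r1a 1.522, Ifih1 -0.8236, Trim30a -1.042, Plin1 1.322, Agpat2 0.87, Dgat2 1.272, Parp14 -0.6781 and Wnt4 2.441. The calls of Plin1 (adjusted p = 0.0292), Agpat2 (0.0345), Dgat2 (0.041), Parp14 (0.038) and Wnt4 (0.0226) were each lost in some of the fits without a library, with adjusted p up to 0.0743, 0.085, 0.0965, 0.0993 and 0.0592.

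The regrouping tests were written before the refits were run. For KO against WT in SAT, 1 of 35 splits, the real one, gave as many called genes (992, highest other 6), and in VAT 1 of 35 (690, highest other 6). For VAT against SAT it was 1 of 35 in WT (6187, highest other 0) and 1 of 35 in KO (7292, highest other 0). For the interaction, 3 of 100 splits, drawn at random within each depot, gave at least as many as the real one (45, highest other 226). The splits with more calls nearly exchange the genotypes within a depot, so they test about the sum of the KO effects and not their difference. In each comparison between groups the real split gave the most calls, and 1 of 35 is the smallest share that this test can reach. Every other split mixes the real groups, which widens the spread within groups, so low counts of calls there were likely in advance. The tests therefore do not exclude that like libraries fell together by chance. A batch that follows genotype or depot would pass every one of these tests.

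The tests of the mitotic pattern were chosen after the result was seen. More leukocytes in the KO preparations, dividing at an unchanged rate, could raise mitotic genes, but markers of macrophages and lymphocytes rose less. Their upper quartile was 0.5558 in SAT and 0.5597 in VAT, under the lower quartiles of the mitotic list (1.25 and 1.389). Of these 33 markers, 0 were called higher in SAT and 4 in VAT. A larger dividing share of the leukocytes present would not need the markers to rise, so this comparison cannot exclude it. The quartiles pool several lineages, so a rise in a single lineage could leave them low and is not excluded either. Igj was called higher in KO SAT, a call lost in 6 of 8 fits without a library. The lymphocyte list was called higher in KO VAT with the preset correlation and not with an estimated correlation. Over both depots and 3 scalings the smallest median of the list was 1.479, but these scalings hardly differed and each centres all genes near 0, so this could not have told a fault of scaling apart. Whether KO mice differed in litter, health or preparation day is open, since genotype may stand for any of these here. Mki67 measured by flow cytometry together with a progenitor surface marker, in littermates, would separate these readings.

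The tests of the lipid pattern in KO VAT were also chosen after the result was seen. KO VAT replicate 4 alone does not carry it, since 10 of the 11 called lipid genes stayed called without that library. RNA of mature adipocytes carried into the KO VAT preparations remains open: 5 of the 30 tested lipid genes had a log2 fold change at or below 0, too few to exclude it. Differentiation of some progenitors could give the same values. Staining of sorted VAT progenitors of both genotypes for PLIN1 would show whether the protein is higher in KO progenitors.

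The tests of the interferon pattern in KO SAT were chosen after the result was seen as well. A single SAT library does not carry it, since over the fits without 1 SAT library the smallest median of the list was 0.4948, the largest adjusted p was 9.26e-13, and 12 to 22 members were called. A share of leukocytes remains open, as the upper quartile of their markers (0.5558) lay above the lower quartile of the interferon list (0.4431). An exposure of the KO cage to infection, which might act on a single depot, cannot be tested with these samples.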

How the results depend on the processing

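Settings other than the one without 2 libraries together were planned before the data were examined, and that one was added after they were seen, as was leaving libraries out for the list of glucocorticoid-induced genes. Counts of called genes moved as follows. In SAT (992), DESeq2 gave 1665, a fit to only the groups compared 509, a minimum of 2-fold 251, adjusted p under 0.01 367, and leaving out 1 library 469 to 1015. In VAT (690) DESeq2 gave 1206, a minimum of 2-fold 273, adjusted p under 0.01 300, and leaving out 1 library 412 to 625. Between depots a minimum of 2-fold gave 2455 in WT (6187) and 3037 in KO (7292), and leaving out 1 library 5395 to 6328 and 6593 to 6968. For the interaction (45) DESeq2 gave 512, a minimum of 2-fold 23, adjusted p under 0.01 1, and leaving out 1 library 7 to 149. The share of higher genes among SAT calls was 58.7%, and 72.1% in the fit to only the groups compared. Fits with fewer libraries have fewer residual degrees of freedom, and otherwise the cause of these moves was not tested. Replicate numbers were not shown to pair the libraries. Between WT SAT and WT VAT, correlations of libraries with the same number were above 0.1 for 3 of 4 and ran from -0.0443 to 0.154 (median 0.1235, other pairs -0.0466), between KO SAT and KO VAT they ran from -0.0473 to 0.0541, and in no pair of groups were all above 0.1. The KO median was 0.0481 for the same number and -0.0151 for other pairs. Between depots, 2 of 4 WT SAT, 3 of 4 WT VAT, 3 of 4 KO SAT and 2 of 4 KO VAT libraries correlated best with their own number. Between genotypes it was 0 or 1 of 4. Pairing of SAT and VAT libraries within a genotype therefore remains possible. With a replicate block edgeR called 873 genes in SAT, 611 in VAT, 6025 and 7192 between depots in WT and KO, and 14 for the interaction (11 with the block nested in genotype). Interaction calls of Ifih1, Trim30a, Plin1, Agpat2, Dgat2 and Parp14 were lost with that block (adjusted p from 0.0507 to 0.0881). Lists called numbered 1 in SAT with an estimated correlation and 8 by fry, against 14 with the preset. The same numbers were 2, 5 and 12 in VAT, 4, 20 and 12 between depots in WT, 3, 22 and 14 in KO, and 0, 3 and 11 for the interaction. Leaving out 1 library gave 12 to 17, 10 to 15, 11 to 13, 14 to 17 and 9 to 12. The odds ratio near Nr4a1 in VAT (2.16) was 1.631 within 20 Mb and 1.455 with DESeq2 calls. Without WT SAT replicate 3 and KO VAT replicate 4 together the counts were 1263, 837, 6838, 8095 and 37. Over 5220 refits of 275 named gene results 4817 stayed as they were, called or not, 325 lost a call, 78 gained one and 0 reversed, and over 2336 refits of 160 list results the numbers were 2165, 110, 61 and 0. Depth limited what could be seen below about 0.0583 CPM in WT VAT replicate 4 to 0.1002 CPM in WT SAT replicate 3, the lowest and highest level that 3 counts give in a library.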

Other observations

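Some gene models outside the naming rule, chosen after the values were seen, separated KO from WT in both depots almost completely. The pseudogene Gm21451 (chromosome 14, 69390854 to 69480287) had 0 counts in all 8 WT libraries and 311 counts in KO SAT and 210 in KO VAT (1.79 ± 0.287 and 1.16 ± 0.384 CPM). The noncoding 1010001B22Rik (chromosome 5, 109995511 to 109996398) had 0 counts in WT and 38 and 42 in KO SAT and KO VAT. Its neighbour Gm15446 (chromosome 5, 109923400 to 109943936), annotated as coding, stood at 0.138 ± 0.0622 CPM in WT SAT and 0.0307 ± 0.0122 in WT VAT, and at 8.25 ± 0.292 and 6.86 ± 0.606 in KO. The pseudogenes Pisd-ps1 (chromosome 11, 3125904 to 3131004) and Pisd-ps2 (chromosome 17, 3076578 to 3084183) went the other way, the first from 52.5 ± 6.12 to 11.8 ± 2.05 CPM in SAT and from 48.7 ± 5.98 to 15.1 ± 1.79 in VAT, the second by -2.13 and -1.78 on the log2 scale. These loci lie on other chromosomes than Nr4a1. Whether reads at these loci also match similar copies elsewhere in the genome was not examined, so the origin of the reads is uncertain. Genotyping strain markers at these loci in the same mice would tell whether they follow the 129S2 background.

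Genes induced by glucocorticoid were lower in KO SAT. Tsc22d3, Klf9 and Klf15 were seen first. Klf9 stood at 640.5 CPM in WT SAT replicate 3 against 358.6 to 395.7 in the other WT SAT libraries, and its call was lost without KO SAT replicate 3 or 4 (adjusted p up to 0.0688). A list of 14 other such genes was then written before its values were looked at, so the tests of this list were not chosen after its result. The idea and its direction came from the same libraries, however. Genes that share an inducer can move together, so the list is not independent support. In SAT its median was -0.4936, 13 of 14 were negative, and 7 were called lower (Per1, Sgk1, Errfi1, Mt1, Mt2, Glul and Rasd1), while 3 of the 14 were called lower without KO SAT replicate 4. In VAT the median was -0.2789, and 11 of 14 were negative. There 1 was called lower (Errfi1, adjusted p = 0.0229), and 0 without WT VAT replicate 1 or 2 or KO VAT replicate 3. The limma list test with an estimated correlation, made for this list alone, gave 0.0171 in SAT and 0.093 in VAT. In fits that left out 1 library, chosen after these values were seen, it gave 0.00485 to 0.036 in SAT (0.0238 without WT SAT replicate 3) and 0.052 to 0.188 in VAT. Mt1 and Mt2 are similar copies. Bcl6 was the only member above 0 in SAT (0.71, not called). Without KO SAT replicate 3, 5 of the 14 were called lower in SAT and 1 was called higher. These values are consistent with weaker glucocorticoid signalling in KO SAT progenitors, and Hsd11b1, which makes active hormone inside cells, fell there too. Time of day and stress at handling change the same genes and might follow genotype here. Treating WT and KO progenitors in culture with a fixed dose of dexamethasone, and measuring Tsc22d3 and Per1, would separate a response of the cells from the hormone level of the mice.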
